A study of Homo sapiens and Mus musculus with 2458 samples.

How the data were processed

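The series holds single-cell transcriptomes from 4 human IDH-mutant gliomas, all exposed to an IDH inhibitor, and from IDH-mutant mouse glioma cells kept with an IDH inhibitor or with DMSO, the solvent control. Per the labels' protocols, fresh tumours were dissociated with papain and stained for CD45, a surface protein of white blood cells, and for CD3, a surface protein of T cells. Viable single cells were then sorted into plates, with light scatter used to leave out doublets. Libraries were made with Smart-seq2, a plate method that reads whole transcripts and uses no molecular identifiers. The droplet, nuclear, methylome and Notch1 knockout data named in the series design were not analysed here.

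The deposited tables hold TPM (each gene's share of a cell's transcripts on a fixed scale) per gene and cell, computed by the authors, and the lowest column total over all cells was 994031. Oligodendroglioma cells, astrocytoma cells and mouse cells stand in separate tables, and the human tables list the same 23686 genes in the same order. The submitters' processing notes name bcl2fastq, Bowtie 0.12.7, R 4.0.1 and the builds GRCh38 and mm10, with no role for each. The quantifier, the annotation and the filter on cells are not given in the sources used here. TPM keeps no sequencing depth, so the depth per cell is unknown, no count model was used, and the number of genes detected per cell stands in as the only measure of library complexity. Some gene symbols are older ones, and genes for T-cell receptor and immunoglobulin constant regions, as well as mitochondrial genes, were not measured in the human tables.

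Groups came from the sample labels: tumour type, tumour, sort gate (CD45+, CD45-, CD3+ or no gate given) and, in mouse, treatment. Oligodendroglioma tumour 1 had 259 CD45- and 141 CD45+ cells, oligodendroglioma tumour 2 had 606 and 147, astrocytoma tumour 1 had 391 CD45-, 146 CD45+ and 275 CD3+ cells, and astrocytoma tumour 2 had 340 cells, and there were 153 mouse cells. Cells are not replicates. The tumour was the replicate in human comparisons, and each mouse treatment was 1 plate with no culture named, so no p-value was computed there. X-inactivation and Y-linked genes were removed, which left 23582 human genes. A minimum of 1500 genes detected per cell was set before the data were examined, as were the designs, the gene lists, the cell type markers and the rule for naming genes. That minimum removed 0 cells, so using all cells moves nothing. No doublet caller was run, because such callers need counts.

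Human cells were clustered with scanpy 1.11.5 on log2(TPM/10 + 1), 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. A cluster was called X-like where at least 3 fixed markers of a class were detected in 25% of its cells and that class had the largest share of its markers detected. A cluster in which a second class had over 0.5 of its markers was called mixed. As both marker sets parted mixed from T-cell-like clusters, the tests on RNA spread and on myeloid cells without T-cell RNA chose CD3+ cells on 1 set (25% of T-cell or 50% of myeloid markers detected) and measured the other, in place of earlier ratios between these clusters. This gave 17 clusters with 1460 glioma-like, 408 myeloid-like, 192 T-cell-like and 145 oligodendrocyte-like cells and 100 cells of a mixed T-cell and myeloid cluster. Glioma-like here covers astrocyte, progenitor and oligodendrocyte-lineage markers that normal precursors share, and malignant cells were not called from DNA. In 1 glioma-like cluster of 218 cells, CSPG4 was among the 10 genes with the largest fold and no glioma marker was. As CSPG4 is a fixed mural or fibroblast marker, these genes held more markers of another class than of glioma. The cluster had a share of 0.83 of glioma and 0.083 of mural or fibroblast markers detected. Of its cells 217 came from astrocytoma tumour 2, which keeps 120 of its 337 glioma-like cells without it. CSPG4 is also on the fixed oligodendrocyte lineage list, so the cluster was kept. That choice was made after the counts with and without it were seen, and the values without it are printed beside the tumour type results.

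Mean TPM over cells was taken per tumour and gate and analysed as log2(mean TPM + 1) for genes with a mean of at least 5 TPM. A fold change on that scale understates the change of low genes. Differences were tested with limma 3.58.1 (eBayes with trend) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05, two-sided. CD45+ and CD45- cells of the same 3 tumours were compared with the tumour as a block, since the labels place both gates in the same tumours. The gates stood on separate plates, except for 1 plate number of oligodendroglioma tumour 2 shared by both, and the block does not remove plate differences. Tumour types were compared on glioma-like cells of 2 against 2 tumours. Gene lists were tested with limma camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation. The lists were the astrocyte, oligodendrocyte lineage and neural progenitor programmes, myelin, G1/S and G2/M cell cycle genes, the Notch pathway, interferon response, MHC class I and class II, hypoxia, dissociation stress, the integrated stress response, cholesterol synthesis, mesenchymal and matrix genes, IDH and 2HG metabolism, microglia, blood-derived myeloid cells, cytotoxic lymphocytes, naive or helper T cells, T-cell checkpoint genes and nuclear RNA, with mitochondrial genes added in mouse. List scores per cell were means of log2(TPM/10 + 1), compared between tumour types by an exact permutation test. Correlations of scores were Spearman coefficients within each tumour, partial on genes detected, with an exact sign-flip permutation test over the 4 tumours. Gene lists in mouse cells were described by the percentile of their median among 10000 random lists matched on expression, as were the 581 tested genes on 1p and the 374 on 19q. Shares of cells carry 95% Clopper-Pearson intervals, which cover counting error only. The other intervals in the tests of technical explanations are 95% bootstrap intervals over 2000 draws of markers or genes. They cover the spread between markers or genes, not between cells, plates or tumours.

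Genes were named by the fixed rule: up to 12 of the largest rises and 12 of the largest falls among genes past the threshold with a mean of at least 20 TPM in the higher group and 1 direction in every tumour or pair. Without a test the rule took the 12 largest ratios each way among genes at 20 TPM or more and detected in at least 20% of cells, and it was extended to the myeloid-like comparison, which was given as values because the design asked for 2 tumours of each type. Up to 4 members of each list and a fixed set of IDH, Notch and lineage genes were added. Genes whose level follows inherited variation were left unnamed. A few other genes that the rule selects are also not printed.

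The limma script was tested on simulated data with 50 genes changed at each size. With each gene's own SD, log2 changes of 1, 2, 4 and 6 were recovered for 0%, 10%, 64% and 66% of genes in the gate comparison (12066 genes), for 0%, 0%, 38% and 54% in the tumour type comparison (11857 genes) and for 0% at every size in the interaction, with 2, 2 and 0 unchanged genes called. With moderated SDs, added after the former was seen, the shares were 2%, 50%, 100% and 100% for the gate, 2%, 26%, 88% and 98% for tumour type, and 0%, 12%, 74% and 94% for the interaction, with 9, 10 and 39 unchanged genes called. Of simulated unmoved lists 4% fell outside the central 95% of random lists, and of lists moved by 1 on the log2 scale 98% fell above it. These genes were simulated as independent, on human expression levels. Lists whose genes vary together can leave the central 95% more often, so the 4% does not carry over to them.

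The alternatives covered pseudocounts of 0.1 and 10, no filter and a filter at 20 TPM, the mean of log values over cells, quantile normalization, eBayes without trend, at least 3000 genes per cell, Leiden resolutions of 0.5 and 2, no tumour block, each tumour left out in turn, and controls for the list scores. Leaving out single clusters, leaving out oligodendrocyte-like cells and matching human cells on genes detected were chosen after seeing the data. Other tools were Python 3.11.15, pandas 2.3.3 and scipy 1.17.1.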

Results

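Smart-seq2 profiles of 2458 cells were analysed, 2305 from human IDH-mutant gliomas and the rest from IDH-mutant mouse glioma cells. IDH-mutant gliomas carry an altered isocitrate dehydrogenase that makes the metabolite 2-hydroxyglutarate, and IDH inhibitors block that enzyme. The human tumours were 2 oligodendrogliomas and 2 astrocytomas, all exposed to an IDH inhibitor. With no untreated tumour among them, an effect of treatment on human cells was not measurable, and the human comparisons are between sort gates and tumour types. Both oligodendrogliomas gave CD45- and CD45+ cells, astrocytoma tumour 1 gave CD45-, CD45+ and CD3+ cells, and astrocytoma tumour 2 gave 340 cells with no gate named. The median number of genes detected per cell was between 4207 and 5651 in CD45- cells and cells with no gate given, between 3718.5 and 4158 in CD45+ cells and 2598 in CD3+ cells. The mouse cells numbered 75 with inhibitor and 78 with DMSO, with a median of 9637 and 10059 genes detected and a first quartile of 8059.5 and 4615.

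The CD45+ gate held mostly myeloid-like cells: 97.9% of cells in oligodendroglioma tumour 1 (95% interval 93.9 to 99.6), 97.3% in tumour 2 (93.2 to 99.3) and 83.6% in astrocytoma tumour 1 (76.5 to 89.2). T-cell-like cells made up 10.3% of that gate in the astrocytoma (5.87 to 16.4) and 0.71% and 0.68% in the oligodendrogliomas. CD45- cells were glioma-like at 99.8% in oligodendroglioma tumour 2 and 95.7% in astrocytoma tumour 1, as were 99.1% of the cells of astrocytoma tumour 2, which have no gate given. In oligodendroglioma tumour 1, CD45- cells were 52.9% glioma-like and 47.1% oligodendrocyte-like (40.9 to 53.4), the latter with myelin genes such as MAG and MAL. The share of oligodendrocyte-like CD45- cells was 0.17% in oligodendroglioma tumour 2 and 4.35% in astrocytoma tumour 1. Myeloid-like cells numbered 0 of the 340 cells with no gate given (95% interval up to 1.08%). These shares follow the sort gates and the plates picked, and describe the plates.

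The gate comparison set CD45+ immune cells against CD45- cells of the same 3 tumours. CD45+ cells had high RGS1, a regulator of G-protein signalling in leukocytes, at a mean of 21250 ± 2128 TPM (SD, n = 3 tumours) against 2.76 ± 3.07 in CD45- cells. The chemokine genes CCL3 (12060 against 1.07 TPM) and CCL4 (8194 against 0.22) and the inflammatory cytokine gene IL1B (2226 against 0.06) rose with them. The complement genes C1QA, C1QB and C1QC (1726, 4471 and 3057 TPM against 0.12, 1.02 and 0.20), the microglial receptor gene TREM2 (1562 against 0.03) and the antigen presentation genes CD74 (8675 against 1.02) and HLA-DRA (5608 against 1.40) rose as well. CCL4L1 and CCL4L2 also rose, but they are near-identical copies with the same value in each cell group, so neither is certain. CD45- cells had more of the proteoglycan gene BCAN (2211 ± 1699 TPM against 25.4 ± 23.6) and of PTPRZ1 (772.8 against 10.8), PTN (780.6 against 10.6), HEPN1 (1004 against 8.34) and BCHE (363.6 against 2.53), genes of glial cells and progenitors. Genes of neurons and secretory cells, TUBB3 (397.2 against 2.51 TPM), CHGB (247.6 against 2.45), CPE (377.1 against 4.55), TRIM9 (relative log2 -5.67) and TUBB4A (475.4 against 9.56), fell in CD45+ cells too, as did S100A16 and CRIP2.

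Of 12066 genes tested with limma, 5151 passed, 1465 higher and 3686 lower in CD45+ cells. The genes named in the gate comparison so far did so at a limma adjusted p of 0.00544 or below with 1 direction in all 3 tumours. As the gates stood mostly on separate plates, a difference between plates was not separable from that between gates. The median difference of all genes was -0.65 on the log2 scale, CD45- cells had more genes detected in each tumour, and the values called relative are taken from that median. Standard errors, p-values and counts of genes that rose or fell belong to the difference before that step, and no relative value was tested by itself. After quantile normalization the median was -0.14 and 3855 genes passed, 1829 higher and 2026 lower, so the share of higher calls went from 28.4% to 47.4%. Without oligodendroglioma tumour 2 the count was 2146. NOTCH1, the receptor gene, fell in CD45+ cells (relative log2 -1.74, with SE 0.35 and limma adjusted p = 0.00232 for the difference before that step), as did OLIG1 (-4.97), OLIG2 (-3.38), PDGFRA (-4.23), SOX4 (-2.87), HES6 (-3.33), DLL3 (-4.13) and GFAP (-3.19). PTPRC, which encodes CD45, was higher by 7.93 and fits the gate labels. HES1 (6.80 against 6.29 TPM), IDH1 (147.2 against 220.3), IDH2 (132.9 against 208.3) and TOP2A (1.89 against 13) did not pass (adjusted p = 0.939, 0.649, 0.12 and 0.565), and HES5 and MKI67 were below the filter.

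**Figure D1:**
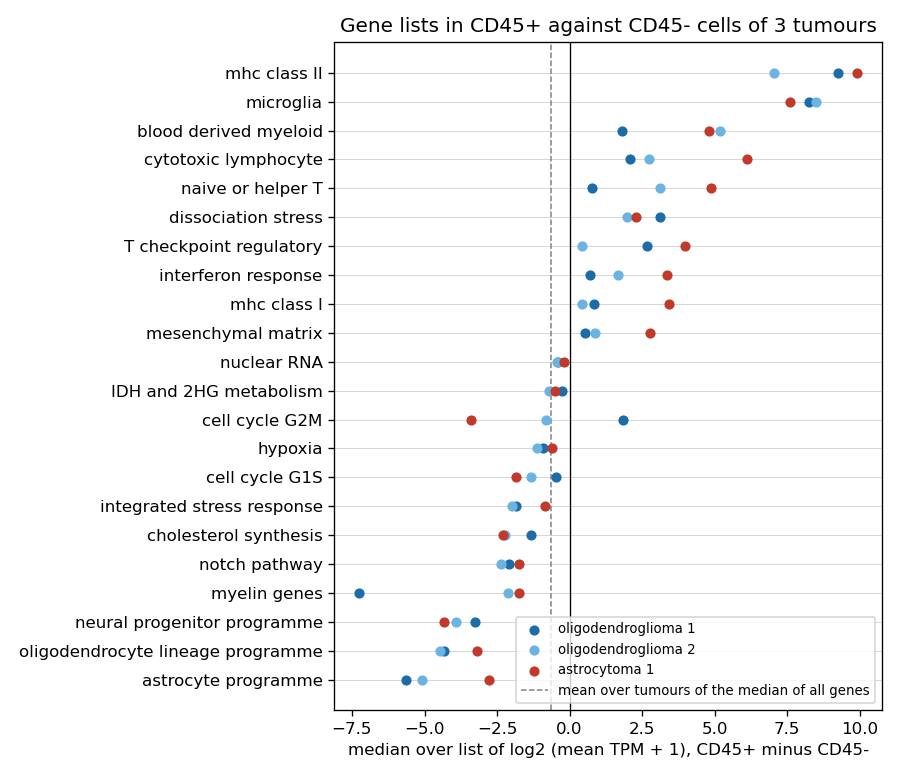
Points give, for each gene list (rows) and each of 3 tumours (colours), the median over list genes of the log2 difference in mean TPM + 1 between CD45+ and CD45- cells; the dashed line is the mean over tumours of the median of all genes. MHC class II lay between 7.06 and 9.91 in all 3 tumours, and the oligodendrocyte lineage list between -4.47 and -3.21.

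Among the fixed lists, all 8 MHC class II genes tested rose in CD45+ cells (relative median 9.66), with HLA-DPA1 at 2269 against 5.14 TPM, and 8 of 9 microglia genes rose (8.76), among them CSF1R (1496 against 0.49), P2RY12 (2404 against 3.15) and CX3CR1 (932.2 against 0.85). Of the blood-derived myeloid list 7 of 10 rose (4.57), led by FCGR3A and CD14, while VCAN, a matrix proteoglycan gene that glioma cells also express, fell (3.83 against 161.7 TPM). Cytotoxic lymphocyte genes rose for 7 of 11 (4.55), and NKG7 and GZMA were listed at 0 in the CD45- cells of all 3 tumours. The naive or helper T list had 2 of 5 higher, among them CD4, and the checkpoint list 2 of 5 higher, HAVCR2 and ENTPD1, both also expressed by myeloid cells, and 1 lower, TOX. Interferon genes rose for 9 of 18 (2.90; BST2 165.8 against 0.77 TPM, IRF7, OAS1, OAS2) and MHC class I genes for 5 of 10 (2.28; B2M 10520 against 2175). Dissociation stress genes rose for 9 of 13 (2.95), with the immediate early genes DUSP1 (5780 against 179.1), ZFP36 (2179 against 23), NR4A1 and ATF3 in front. In the mesenchymal and matrix list 5 of 11 rose (1.29; ANXA1, TIMP1) and FN1 fell.

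Falling lists were led by the oligodendrocyte lineage programme, where 20 of 20 fell (relative median -3.43; APOD, OMG, TNR), the astrocyte programme with 17 of 22 lower and 1 higher (-3.80; SPARCL1 35 against 1812 TPM, CLU 44.5 against 1898) and the neural progenitor programme with 16 of 18 lower (-3.28; NFIB, STMN4). Of the Notch pathway 8 of 11 fell (-1.74), among them the target gene HEY1 (-4.34) and the ligand gene DLL1 (-2.59). Cholesterol synthesis genes fell for 9 of 13 (-1.52; DHCR7, LSS, MSMO1). Myelin genes fell for 11 of 14 (-3.05; MAG 12.7 against 553.7 TPM), and oligodendrocyte-like cells were 47.1% of CD45- cells in 1 tumour. G1/S genes had 6 of 12 lower and 1 higher (-0.44), hypoxia genes 5 of 11 lower and 2 higher (-0.58; BNIP3 and ENO2 lower, ADM higher), integrated stress response genes 5 of 10 lower and 1 higher (-0.70; PHGDH 11.7 against 268.5 TPM), IDH and 2HG metabolism genes 2 of 11 lower (0.23; GLUD1, TET1), G2/M genes 1 of 13 lower (-0.16; PLK1) and nuclear RNA 1 of 4 in each direction (0.29; NEAT1 higher, MEG3 lower).

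Camera passed 16 of 22 lists at the preset correlation: the 10 from MHC class II to the mesenchymal and matrix list as higher, and the 6 from the oligodendrocyte lineage programme to myelin genes as lower. With an estimated correlation 0 passed, and the lowest adjusted p = 0.293. The G1/S, G2/M, hypoxia, integrated stress response, IDH metabolism and nuclear RNA lists did not pass (adjusted p = 0.231, 0.982, 0.998, 0.982, 0.724 and 0.976), and for G2/M, hypoxia and IDH metabolism the direction of camera and the sign of the relative median differed. The myelin call (adjusted p = 0.0219) ended without the oligodendrocyte-like cells (adjusted p = 0.508), without the tumour block (0.0763), as a mean of logs (0.134) and without oligodendroglioma tumour 1 (0.0546). The checkpoint call (0.0219) ended without the astrocytoma (0.215), at 20 TPM or more (0.0751) and after quantile normalization (0.0793). Adjusted over the list alone, members past the threshold numbered 18 lower in the astrocyte programme, 17 lower in neural progenitor, 12 lower in myelin, 9 lower in Notch, 10 lower in cholesterol synthesis, 11 higher in dissociation stress, 3 higher in naive or helper T, 3 higher and 6 lower in hypoxia and 2 higher in the integrated stress response. In the other lists the count adjusted over the list alone equalled that over all genes.

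Whether the gate difference varied with tumour type was tested by an interaction of the 2 oligodendrogliomas against 1 astrocytoma. PDPN, which encodes podoplanin, was higher in CD45+ cells by 6.14 and 6.38 (log2) in the oligodendrogliomas and -0.86 in the astrocytoma (adjusted p = 0.138). SERPINA3 was lower in CD45+ cells by -6.94 and -6.60 in the oligodendrogliomas and by -0.20 in the astrocytoma (adjusted p = 0.17). TOP2A differed by 2.35 and -0.22 against -5.28, and PTGDS by -10.5 and -5.23 against -1.31. FAM64A, PLN, RASL11B and TRIM48 were the other large positive terms, and CNN2, CLC, an eosinophil gene, and HBA2, a red cell gene, were among the other negative ones. With limma 0 of 12066 genes passed and 1113 had an unadjusted p under 0.05 (1104 at pseudocount 10). These genes were named by size alone.

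Tumour types were compared on glioma-like cells, with both types under treatment; the study asks about lineage differentiation in oligodendroglioma, and these cells carry the lineage genes. Oligodendroglioma cells had more APOE, a lipid carrier of astrocytes, at 2401 ± 698.9 TPM (SD, n = 2) against 69.6 ± 25.1 in astrocytoma cells (log2 difference 5.11 ± 0.46 SE, limma adjusted p = 0.0312), and more of the glycolytic astrocyte gene ALDOC (2426 ± 105.5 against 165.5 ± 46.1, adjusted p = 0.0434). LPL, which encodes lipoprotein lipase (244.6 against 3.92 TPM), GABRB1, a GABA receptor subunit (197.8 against 2.32), HTRA1, a secreted protease (278.4 against 13.2), AZGP1 (125.5 against 0.22), SDS (91.6 against 0.19) and C3orf14 (138.5 against 1.39) rose as well, with adjusted p between 0.0259 and 0.0456. DRG2, RASL10A, ENPP5, TBC1D10A and KCTD12 rose by log2 3.98 to 4.95. Astrocytoma cells had more TOP2A, the topoisomerase of dividing cells (46.5 ± 9.94 against 0.71 ± 0.62 TPM), LNX1 (135.7 against 4.86) and ZNF560 (48.3 against 0.22).

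**Figure D2:**
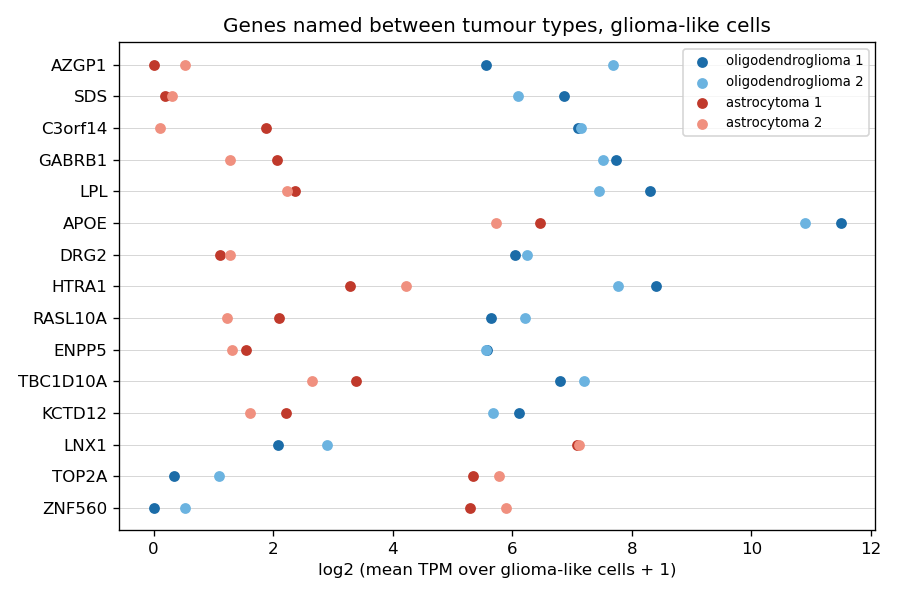
Each point is the log2 of mean TPM + 1 over glioma-like cells of 1 tumour, for the 15 genes named by size between tumour types. For LPL the oligodendroglioma mean was 244.6 TPM and the astrocytoma mean 3.92 TPM.

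Of 11857 genes 21 passed, 18 higher and 3 lower in oligodendroglioma, and 2003 had an unadjusted p under 0.05. The count is fragile: it was 31 without the CSPG4 cluster and 0 to 64 over all settings. All 21 kept their sign in every setting but 1. Without the cycling cluster led by TOP2A 20 of them were counted as keeping it, and that count leaves out any gene that fell under the filter there. Different clusters held most glioma-like cells of each tumour, and tumour type cannot be told apart from table and plates. Median genes detected were 4163 and 4204 in oligodendroglioma against 5478 and 5656 in astrocytoma cells. NOTCH1 (44 against 34.1 TPM), HES1 (9.36 against 3.37), HES6 (135.5 against 78.4), DLL3 (70.7 against 122.1), GFAP (1219 ± 1507 against 870 ± 1080), OLIG1 (197.4 against 162.9, but -0.12 as the fitted log2 difference, as oligodendroglioma tumour 2 carries the mean), OLIG2 (26.1 against 32.1), IDH1 (141.4 against 282.2), IDH2 (217.8 against 189.4), SOX4 (81.1 against 249.2) and PDGFRA (93.1 against 409.9) did not pass, with adjusted p from 0.0888 for PDGFRA upward.

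The astrocyte programme stood higher in oligodendroglioma for 22 of 22 genes (median log2 difference 2.24; CST3 9391 against 344.8 TPM, CRYAB 4441 against 257.4), 2 of them past the threshold over all genes and 16 adjusted over the list alone. G2/M genes stood lower for 15 of 15 (-3.72; UBE2C 3.28 against 115.8 TPM, CDK1 4.42 against 72.6, CCNB2 0.68 against 39.5), 1 past the threshold over all genes and 15 adjusted over the list alone. For G1/S genes 12 of 13 stood lower (-1.64; CDC6, GINS2, RRM2, MCM2), 0 over all genes and 6 over the list alone, and for neural progenitor genes 13 of 19 (-1.31; TUBB3 138.8 against 747.8 TPM, ELAVL4, INSM1), 0 and 8. INSM1 and TUBB3 were among the top genes of the glioma-like cluster led by CRABP1, with 93 CD45- cells of astrocytoma tumour 1. That cluster had a share of 0.511 of glioma markers and 0.455 of neuron markers detected, and without it 1 gene passed between tumour types. MHC class I genes stood higher for 9 of 9 (1.71; TAP1 67.3 against 16.3 TPM, PSMB8, PSMB9), 0 and 6, and interferon genes for 9 of 10 (0.70; IFIT1 37.4 against 8.69, IFIT3), 0 and 2. Dissociation stress genes stood lower for 11 of 12 (-1.17; HSPA1B 120.9 against 861.9 TPM, DNAJB1 272.2 against 1772, EGR1), 0 in both counts. Myelin genes stood higher for 6 of 7 (1.33), 0 over all genes and 2 higher and 1 lower, MBP, over the list alone.

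These 8 lists of 17 passed camera, at an adjusted p of 0.0408 for myelin and below for the others. With an estimated correlation 0 passed and the lowest adjusted p = 0.531. Without the cycling cluster the G2/M and G1/S calls ended (adjusted p = 0.675 and 0.454), and without the CSPG4 cluster 6 lists passed, with interferon (0.27) and myelin (0.252) lost. With astrocytoma tumour 1 left out 5 lists passed and the neural progenitor (0.0753), interferon (0.498) and myelin (0.391) calls ended, with astrocytoma tumour 2 left out the dissociation stress call ended (0.202), and with oligodendroglioma tumour 2 left out the dissociation stress (0.0767) and myelin (0.392) calls ended. The myelin call also ended at 20 TPM or more (0.494), with no filter (0.131, as did interferon), at pseudocount 0.1 (0.0505) and without the CRABP1 (0.0817) or the cycling cluster (0.0733). The oligodendrocyte lineage list was split, 10 genes higher and 10 lower (median 0.003, adjusted p = 0.695), with GPR17 and TNR higher and PDGFRA and CSPG4 lower by value, and passed as higher when oligodendroglioma tumour 1 (adjusted p = 0.000407) or astrocytoma tumour 2 (0.0161) was left out. Adjusted over the list alone, 0 of its genes passed higher and 1 lower. The Notch pathway (8 of 13 higher, HEY1 750.1 against 173.1 TPM, DLL1 lower by log2 -1.65; 2 higher and 1 lower over the list alone), hypoxia (4 of 10 higher), integrated stress response (6 of 10; 2 over the list alone), cholesterol synthesis (3 of 13), mesenchymal and matrix (2 of 8 higher, LGALS1 and LGALS3; 2 over the list alone), IDH and 2HG metabolism (6 of 11; 1 over the list alone), checkpoint (3 of 4) and nuclear RNA (2 of 4; 1 lower over the list alone) lists did not pass, at adjusted p of 0.248 and above. Other immune lists had under 3 genes tested.

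The scores of single cells were averaged per tumour. The astrocyte score averaged 4.14 ± 0.82 (SD, n = 2) in oligodendroglioma and 1.47 ± 0.04 in astrocytoma cells, the neural progenitor score 1.45 ± 0.27 against 2.31 ± 0.15 and the cell cycle score 0.28 ± 0.03 against 0.75 ± 0.05. Exact permutation tests gave p = 0.333 for each, the smallest value that 2 against 2 tumours allow. The oligodendrocyte lineage score was 1.80 ± 0.83 against 1.90 ± 0.89 (exact permutation p = 0.667). Without the CSPG4 cluster the differences were 2.31 for astrocyte, -0.74 for neural progenitor, -0.68 for cell cycle and 0.27 for oligodendrocyte lineage scores, against 2.68, -0.87, -0.47 and -0.10 with it.

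Within tumours, astrocyte and neural progenitor scores opposed each other in 3 of 4 tumours, with partial Spearman coefficients of -0.51, -0.44 and -0.40, and were near 0 in astrocytoma tumour 2 at -0.03 (mean -0.35 ± 0.21 SD; exact sign-flip permutation p = 0.125, the smallest possible; adjusted over 6 pairs 0.375). Astrocyte and oligodendrocyte lineage scores opposed each other in 3 of 4 tumours (mean -0.43 ± 0.35, exact permutation p = 0.25, adjusted 0.5), with 0.07 in astrocytoma tumour 1. The oligodendrocyte lineage and cell cycle scores had a mean of -0.07 ± 0.06 (negative in 4 of 4, exact permutation p = 0.125, adjusted 0.375). Oligodendrocyte lineage and neural progenitor scores had coefficients of 0.48 and 0.40 in the oligodendrogliomas and -0.22 and -0.10 in the astrocytomas (mean 0.14). Astrocyte with cell cycle (mean -0.01) and neural progenitor with cell cycle (0.04) were near 0 with both signs among tumours. Cells of 1 tumour are not independent replicates, and without the CSPG4 cluster the 6 means, in the order astrocyte with neural progenitor, with oligodendrocyte lineage and with cell cycle, then oligodendrocyte lineage with cell cycle and with neural progenitor, then neural progenitor with cell cycle, were -0.36, -0.43, -0.10, -0.002, 0.11 and 0.05.

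Loss of chromosome arms 1p and 19q defines oligodendroglioma, so genes there check the type labels as groups. The genes tested on 1p had a median log2 difference of -0.91 between oligodendroglioma and astrocytoma cells, and 85.7% of them were lower in oligodendroglioma. On 19q the median was -0.78, with 84.2% lower. The other 9294 autosomal genes had a median of -0.03, with 51.8% lower. Both arms lay below all 10000 random lists matched on expression. Positions were known for 10249 of the 11857 genes.

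Myeloid-like cells were compared as values: the design asked for 2 tumours of each type, astrocytoma tumour 2 gave 0 such cells, and a test of 2 tumours against 1 was not run. Microglia genes were close between types (median log2 difference 0.19, oligodendrogliomas minus the astrocytoma), with P2RY12 at 2297 and 3081 TPM in the oligodendrogliomas and 2205 in the astrocytoma, and TMEM119 higher by 0.59. All 8 MHC class II genes were lower in both oligodendrogliomas (median -1.93, with -1.17 in tumour 1 and -2.85 in tumour 2; HLA-DRA 4527 and 1695 against 12360 TPM, CIITA, their master regulator, 32.5 and 6.22 against 72.9). Interferon genes were lower in both for 16 of 18 (-1.26, and -0.34 as a mean of logs; MX1 18.4 and 28.1 against 84.8; IFI27 listed at 0 in both), as were 10 of 10 MHC class I genes (-0.73; B2M 6409 and 9262 against 13700). Of the blood-derived myeloid list 7 of 10 were lower in both (-2.32, with -3.75 in tumour 1, -0.88 in tumour 2 and -0.22 as a mean of logs; S100A8, FCN1 and LYZ, 93.3 and 52 against 528.7), while MRC1 was higher (45.3 and 151.1 against 0.02). The heat shock genes HSPA6 (68.3 and 17.2 against 1070), HSPA1B (462.4 and 144.8 against 4618), DNAJB1 (542.2 and 265.1 against 4578) and HSPB1 (97.2 and 82.6 against 812.5) were lower. The dissociation stress list that holds HSPA1B and DNAJB1 was split, with 4 of 13 genes higher in both, among them IER2 (2504 and 672.9 against 443.8), and 3 lower (median 0.29, with 0.83 in tumour 1, -0.31 in tumour 2 and 1.13 as a mean of logs). LYVE1 (182.2 and 827.8 against 15.5), RNASE1 (355.5 and 3034 against 52.1) and MYOZ2 were higher, as were DBI and SESN2. The cells came mostly from a different cluster in each tumour.

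CD3+ cells of astrocytoma tumour 1 were set against its CD45+ cells, again as values without a test. All 12 cytotoxic lymphocyte genes were higher in the CD3+ gate (median log2 ratio 2.98), with NKG7 at 1789 TPM (log2 ratio 3.15), GZMA at 1203 against 121.2 TPM and IFNG at 177.6 against 10.1. Checkpoint genes were higher for 7 of 9 (2.14; PDCD1 294.2 against 20.4, LAG3 43.4 against 0.61), naive or helper T genes for 7 of 8 (1.28; CD40LG 91.5 against 0.02, CCR7 51.5 against 0.91) and MHC class I genes for 10 of 10 (1.14; TAP1, PSMB9). The T-cell signalling genes LAT (341.6 against 16.5), PTPRCAP (1664 against 148.2), GRAP2, SIT1 and TRAT1 were also higher. Microglia genes were lower for 9 of 9 (-1.65; P2RY12 550.3 against 1931), and dissociation stress genes for 12 of 13 (-1.20; JUN 31.8 against 328.6). T-cell-like cells were 63.6% of the CD3+ gate (57.7 to 69.3) and mixed cells 34.5% (28.9 to 40.5).

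The mouse cells are the part of the data with both treatment arms. Cells with inhibitor had 410.5 TPM of Hmox1, the haem oxygenase induced by oxidative stress, against 41.4 with DMSO (log2 ratio 3.28), and more of the heat shock genes Hspa1a (41.1 against 1.49) and Cryab (369.2 against 66.5). Stmn3 (52.2 against 7.36 TPM), which regulates microtubules in neurons, and Pcp4l1 (30.4 against 4.16) were higher, and so were the short non-coding RNAs Rn7sk (59.8 against 8.38), Rpph1, and Rn7s1 and Rn7s2 (115.7 against 5.80 in both, copies whose values are identical and so uncertain). Slpi, a protease inhibitor gene, was lower (23.7 against 251.9 TPM, log2 ratio -3.35), as were Igf1 (4.31 against 39.3) and the interferon-induced Ifi27l2a (13.4 against 71), and most other falls named by the rule were of predicted genes such as Gm10925 (285.3 against 2879). S100a6, outside the rule and named after its values were seen, was lower by more than Slpi (24.4 against 337.8 TPM). Slpi was detected in 14.7% of inhibitor cells and 25.6% of DMSO cells, and Hspa1a in 24% and 19.2%, so few cells set their means, and averaging log values over cells gave -0.74 for Slpi, 0.32 for Hspa1a and 0.97 for Hmox1. Idh1 (76.8 against 87.2 TPM), Idh2 (49.4 against 71.5), Notch1 (18.9 against 27.5), Hes1 (16.5 against 18.3), Hes6 (21.6 against 35.6), Gfap (9.70 against 6.43), Olig1 (95.4 against 132.6), Olig2 (28 against 27.7), Sox4 (82.4 against 74.4), Mki67 (81.9 against 97.8) and Top2a (177.2 against 199.7) lay closer together, Pdgfra and Dll3 were under 1 TPM, and Hes5 was listed at 0.

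**Figure D3:**
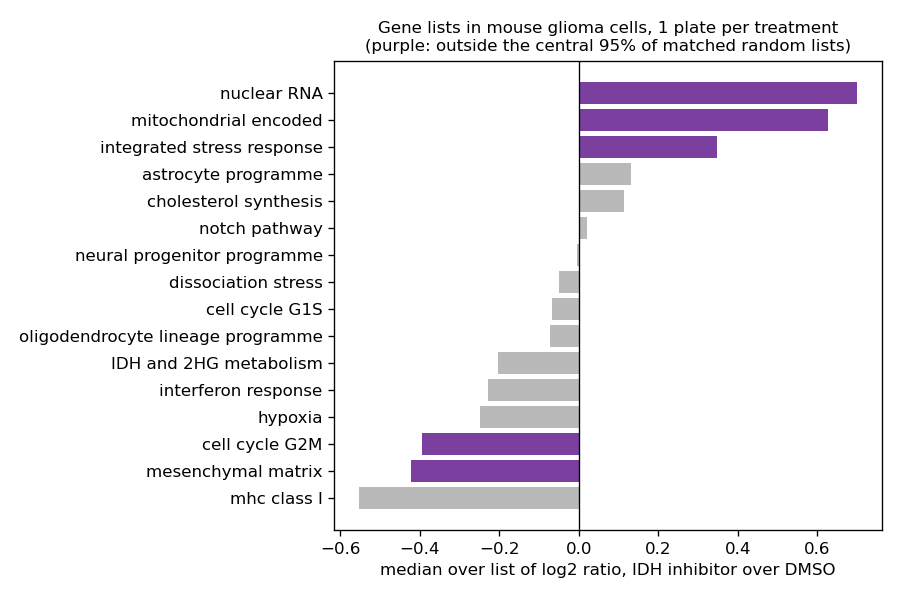
Bars give the median over list genes of the log2 ratio of mean TPM + 1, inhibitor over DMSO, in 75 and 78 mouse cells; purple bars lie outside the central 95% of random lists matched on expression. Nuclear RNA (0.70), mitochondrial (0.63) and integrated stress response genes (0.35) lay above, and G2/M (-0.39) and mesenchymal and matrix genes (-0.42) below, with nuclear RNA and G2/M back within the central 95% in cells matched on genes detected.

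Of the fixed lists in mouse, 9 of 9 mitochondrial genes were higher with inhibitor (median log2 ratio 0.63, percentile 100; mt-Atp6 34470 against 20640 TPM, mt-Co2, mt-Nd2), and mitochondrial RNA was 21.3% of TPM against 17.3%. In matched cells the median was 0.64, at percentile 100. Despite their high means, mt-Atp6 was detected in 100% of inhibitor and 87.2% of DMSO cells and mt-Co2 in 100% and 82.1%. For mt-Nd2 both were 100%, and why some DMSO cells lacked the former was not tested. Integrated stress response genes were higher for 8 of 10 (0.35, percentile 99.6), led by Ddit3, the stress transcription factor CHOP (186.8 against 57.6), and Slc7a11, the cystine transporter (20.6 against 9.98), with Phgdh and Atf5 lower. Nuclear RNA was higher for 2 of 3 (0.70, 99.4; Malat1, Neat1), and in matched cells its median was 0.34 at percentile 93.8, within the central 95%. G2/M genes were lower for 15 of 16 (-0.39, percentile 0.18; Ube2c 125.4 against 273.1, Cdc20, Plk1), but among 50 cells per treatment matched on genes detected the median was -0.07. Mesenchymal and matrix genes were lower for 6 of 8 (-0.42, percentile 1.57; Anxa2, Vim). The astrocyte programme was higher for 10 of 15 (0.13, percentile 95.9; Clu 74 against 25) and reached 0.19 at percentile 98.9 in matched cells, while the oligodendrocyte lineage (-0.07, 45.5), neural progenitor (-0.005, 64.8), Notch (0.02, 62.1), G1/S (-0.07, 46.4), cholesterol synthesis (0.11, 91.1), dissociation stress (-0.05, 44.9), hypoxia (-0.25, 16.7), IDH and 2HG metabolism (-0.20, 20.9), interferon (-0.23, 29.1) and MHC class I (-0.55, 2.54) lists lay within the central 95%. Averaging log values over cells put hypoxia (-0.24, percentile 0.925), IDH and 2HG metabolism (-0.18, 1.61) and dissociation stress (-0.14, 1.88) below it and G2/M (-0.07, 17.8) within it. Myelin and immune lists had 0 or 1 gene measured above the filter. Each treatment is 1 plate of cells, so these differences have no replicate check and compare 2 plates.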

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

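The interaction test on gene lists was not in the design and was run after the genes had been seen, as were the tests on RNA spread, on myeloid cells without T-cell RNA and on other splits, while the test on 2 cells in 1 well was written before. A signal outside the planned classes was the mixed cluster: 34.55% of CD3+ cells in astrocytoma tumour 1, 95 cells, carried T-cell and myeloid markers together, with CD3D at a mean of 665.9 TPM (2427 in T-cell-like and 0.18 in myeloid-like cells) and CD14 at 1277 (59.3 and 1206).

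In the mixed cells T-cell markers stood at 0.295 relative to T-cell-like cells, which held some myeloid RNA themselves (C1QB at 307.7 TPM). Myeloid markers stood at 0.92 relative to myeloid-like cells, which gave a sum of 1.22. A T cell and a myeloid cell in 1 well would give about 1, or 0.7 to 1.3 as written beforehand. The 95% bootstrap interval of the sum, 1.03 to 1.32, leaves out 1 and reaches past 1.3. It redraws markers and not cells or wells, so it covers the spread between markers only. Among CD3+ cells chosen on myeloid markers alone, a share of 0.929 (0.865 to 0.969) had T-cell markers at 0.1 or more of the level in the other CD3+ cells. Of CD45+ cells chosen alike the share was 0.0315, but these stood on other plates, where T-cell-like cells were 10.3% and not 63.6%. Most of these CD3+ wells thus held T-cell RNA. Spread from other wells of those plates could also place it there, so myeloid cells without T-cell RNA of their own stay open. RNA spread between wells stays open, as its test could not decide. Among CD3+ cells chosen on T-cell markers alone, 0.354 (0.297 to 0.414) had myeloid markers under 0.1 of the myeloid-like level. Spread would leave under 0.1 of cells and its absence over 0.5. However, that choice kept nearly every CD3+ cell, and so nearly all mixed cells. Mixed cells carry myeloid markers by definition and lower the share, so a share under 0.5 does not speak for spread. Mixed cells had a median of 4193 genes detected, against 2282 in T-cell-like and 3861.5 in myeloid-like cells, and more MRC1 than the myeloid-like cells of the CD45+ gate (11.1 against 0.02 TPM). The sort excluded doublets by scatter and selected CD3, so a T cell held by or taken up into a macrophage may give the same sum of 1.22, and no biological explanation was tested.

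Camera on the interaction passed 10 of 22 lists for the gate difference in the 2 oligodendrogliomas against that in 1 astrocytoma, a layout that does not separate tumour type from that 1 tumour and takes the spread behind its p-values from the 2 oligodendrogliomas alone. The median interaction was -2.28 for the astrocyte programme, -1.32 for oligodendrocyte lineage, 1.15 for neural progenitor, -2.64 for myelin, 1.33 for G1/S, 3.64 for G2/M, -1.84 for interferon, -2.45 for MHC class I, -2.12 for MHC class II and -3.38 for cytotoxic genes (adjusted p of 0.0117 or below). With an estimated correlation 0 passed, at an adjusted p of 0.566 for each of these lists. The MHC class I gate difference was 0.83 and 0.41 in the oligodendrogliomas and 3.41 in the astrocytoma. For myelin it was -7.25 in oligodendroglioma tumour 1, where 47.1% of CD45- cells were oligodendrocyte-like, and -2.13 and -1.76 in the other 2 tumours. For cytotoxic genes it was 2.07 and 2.72 against 6.10, with T-cell-like shares of CD45+ cells of 0.71% and 0.68% against 10.3%. The hypoxia list was flagged by sign alone: relative to all genes its gate difference was -0.39 and -0.45 in the oligodendrogliomas and 0.07 in the astrocytoma (difference -0.49), and the interaction test did not call it (adjusted p = 0.223). Of 6 score correlations 0 had an outlying tumour by Dixon's rule.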

How the results depend on the processing

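Of 1706 alternative values 1172 were counted as kept and 52 reversed, and the others moved or lost a call. Kept meant the same call and sign for a gene, a similar number for a count and a value inside the main interval for a share. For score differences and correlations it meant the same sign only, whatever the size. Leaving out clusters or oligodendrocyte-like cells and matching human cells were chosen after seeing the data, and where no cause is named, the cause was not tested. The interaction with 1 oligodendroglioma left out was not run, as 0 residual degrees of freedom remain. Where leaving out a tumour leaves 1 in an arm, limma assumes that it varies like the others. Depth is unknown in TPM, so its limit on low genes could not be measured.

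For CD45+ against CD45- cells, 5151 genes passed, 3184 at 20 TPM or more (fewer genes tested), 5264 without the tumour block and 2146 to 4767 with 1 tumour left out; 16 lists passed, 15 without the block and 0 with an estimated correlation. HES1 reversed from 0.05 to -0.0346 as a mean of logs and -0.24 without oligodendrocyte-like cells (-0.17 to 0.23 with 1 tumour left out), and IDH1 ranged from -0.92 to 0.57.

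Between tumour types 21 genes passed; the count was 0 with all cells of the gate, matched cells, the mean of logs, no filter or no trend, 64 at 20 TPM or more, 7 and 5 at pseudocounts 0.1 and 10, 1 after quantile normalization, 1 without the CRABP1 cluster, 7 without the TOP2A cluster and 0 to 41 with 1 tumour left out. Of 17 lists 8 passed, 0 with an estimated correlation, 5 without the TOP2A cluster and 5 to 9 with 1 tumour left out. Without the CSPG4 cluster GFAP was -0.082, OLIG1 0.20 and OLIG2 0.30; in matched cells GFAP was -0.0526 and NOTCH1 -0.26; as a mean of logs IDH2 was -0.20; and OLIG1, -0.12 as fitted, was 0.26 with all cells of the gate and 0.0524 in cells with 3000 genes. With 1 tumour left out GFAP ranged from -1.46 to 2.47, IDH1 from -1.62 to 0.0695, OLIG1 from -1.24 to 1.00 and OLIG2 from -0.84 to 0.41. On 1p the difference was -0.58 at pseudocount 10 and -0.998 at 20 TPM or more, and on 19q -0.49 and -0.85.

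Score differences reversed as follows. With control genes subtracted they were 0.23 for oligodendrocyte lineage, 0.14 for Notch, 0.0243 for hypoxia, 0.0375 for IDH and 2HG metabolism, 0.0075 for naive or helper T and 0.0564 for checkpoint genes; in matched cells 0.12 for oligodendrocyte lineage, 0.0451 for Notch, 0.0088 for hypoxia and 0.0098 for naive or helper T; without the CSPG4 cluster 0.27 for oligodendrocyte lineage, 0.012 for Notch, -0.0138 for interferon, 0.0006 for naive or helper T and 0.0172 for checkpoint genes; and nuclear RNA was -0.10 on log2(TPM + 1). With 1 tumour left out the ranges were -0.73 to 0.53 for oligodendrocyte lineage, -0.0783 to 0.022 for MHC class II, -0.11 to 0.15 for blood-derived myeloid, -0.008 to 0.0358 for cytotoxic, -0.0339 to 0.023 for naive or helper T, -0.0371 to 0.0225 for checkpoint and -0.52 to 0.60 for nuclear RNA. Without the partial step the mean correlation with cell cycle was 0.0041 for astrocyte and 0.0276 for oligodendrocyte lineage scores, and the former ranged from -0.0428 to 0.0247 with 1 tumour left out.

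In mouse, Rn7s1 was 4.29 and 2.99 at pseudocounts 0.1 and 10, 4.04 in cells with 3000 genes, 0.77 as a mean of logs and 4.35 in matched cells; Slpi was -3.40, -2.96, -3.24, -0.74 and -1.70 in that order; Gm8292 was 0.63 in cells with 3000 genes and 0.0912 as a mean of logs. The mixed share of CD45+ cells in oligodendroglioma tumour 2 was 5.44% at Leiden resolution 2. The cytotoxic ratio of CD3+ to CD45+ cells was 2.77 at pseudocount 10, and the microglia difference of myeloid-like cells was 0.31 as a mean of logs and 0.0586 to 0.17 with 1 oligodendroglioma left out.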

Other observations

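The tests on genes detected and on cycling cells between tumour types, on handling stress and plates in mouse, and on other splits were written after the results were seen. The dissociation stress score of glioma-like cells was 1.38 ± 0.03 (SD, n = 2 tumours) against 2.92 ± 0.67 in astrocytoma (exact permutation p = 0.333, the smallest possible), and its heat shock members HSPA1B and DNAJB1 did not pass limma (adjusted p = 0.178 and 0.184). MHC class I scores of glioma-like cells were 2.41 ± 0.20 against 1.46 ± 0.73, with 0.95 in astrocytoma tumour 1 and 1.98 in astrocytoma tumour 2. Cholesterol synthesis scores were 1.37 ± 0.16 against 1.81 ± 0.24. In the CD3+ gate 7 of 9 mesenchymal and matrix genes were higher than in CD45+ cells (median 1.46).

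For the 5151 genes called between gates, the 6 means allow 10 splits into 3 and 3, of which 1, the real one, gave as many genes and the highest other gave 0. With 10 splits a share under 0.05 is not possible. The other splits also leave the gate difference in the residual spread, which lowers their counts, so the 0 decides nothing.

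The median absolute log2 difference of the 21 genes called between tumour types was 4.81 in cells matched on genes detected against 4.34 in all, a ratio of 1.11 (0.918 to 1.21), and 0 genes passed there, for a reason that was not tested. Without the cycling cluster the ratio was 0.977 (0.858 to 1.03). Both intervals redraw the 21 genes and not cells or tumours. The 18 higher genes would need a median of 3720% of myeloid RNA, more than a well can hold, and myeloid markers stood at 0.0595% of their level in myeloid-like cells, 1.6e-05 of that need. For these genes, chosen for their difference in the same cells, the values argue against fewer genes detected as the whole cause. For the 18 higher genes, by their median, the needed share also argues against myeloid RNA as the whole cause. The 0.0595% adds little, as these wells were kept for lying in clusters named glioma-like. The cycling ratio mostly follows the 18 higher genes and decides nothing for TOP2A, among the 3 lower ones. Without the cycling cluster 7 genes passed. A difference between plates and tables was not separable from tumour type.

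The integrated stress response list was higher on the mouse inhibitor plate (median 0.35). In cells matched on genes detected it stayed at percentile 99.81, while G2/M and nuclear RNA moved back inside the central 95%. Cells with few genes stay open, as the ratio of medians was 1.05 (-0.192 to 2.26) and the interval of the matched median, 0.0761 to 0.942, reaches below 0.205, the upper limit of the central 95% of random lists. Handling stress of the plate stays open: the dissociation stress list stood at percentile 44.91, but its members went both ways, 5 higher and 6 lower, and its median of -0.05 has an interval of -0.827 to 1.52 that holds the change to be explained. The intervals for both lists redraw list genes and not cells or plates. With 1 plate per treatment, an effect of the inhibitor on Ddit3 and Slc7a11 is a hypothesis that could equally be a difference between plates or cultures.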
